A study of Macaca fascicularis with 8 samples.

How the data were processed

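Polyadenylated RNA from cynomolgus monkey (Macaca fascicularis) embryonic stem cells (ESCs) was sequenced in 8 libraries, 4 from primed cells and 4 from dome-shaped cells. Per the labels' protocols, messenger RNA was fragmented, reverse transcribed with random primers and sequenced on a HiSeq instrument after TruSeq preparation, and no strand-specific step is recorded. Primed cells grew as flat colonies in a conventional monkey ESC medium mixed with a commercial human stem cell medium. Dome-shaped cells grew in a medium that contained leukaemia inhibitory factor (LIF), basic fibroblast growth factor, transforming growth factor beta, insulin, vitamin C and kinase inhibitors, namely PD0325901 against MEK, CHIR99021 against GSK3, SB202190 and SB203580 against p38 and SP600125 against JNK. The medium, the colony shape and the group coincide, so none of them can be separated from the others here.

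The authors deposited 1 table of RPKM values (reads scaled by gene length and by library depth) for the 8 libraries, with a query length for most genes and with best protein matches per gene. The submitters' processing notes name Bowtie2 2.0.6, TopHat2 2.0.9 and HTSeq 0.6.1. The genome build and the annotation are not given in the sources used here. The table had 33138 rows, of which 17 were blank and left out, and the remaining 33121 genes were 30246 with identifiers beginning ENSMMUG and 2875 with identifiers of the authors' own. The columns for dome-shaped replicates 1, 2 and 3 lacked the closing characters of their titles. Those of replicates 1 and 2 were assigned because no other title held the same number, and that of replicate 3 because the only other title with the same start had a column of its exact name; the remaining 5 columns carried their titles exactly. The columns of other samples numbered 0.

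Gene symbols came from the deposited table for 4302 genes. For other genes the protein matches with at least 0.95 of the best score and at least 85% identity were used: 7354 symbols were looked up by RefSeq accession in the gene table of assembly T2T-MFA8v1.1, 1940 were quoted in the match itself and 127 came from protein names paired by hand with genes of the fixed lists, without reference to the groups. Where the table and RefSeq both gave a symbol, the symbols were equal for 90.9% of 2223 genes. Of the genes tested, 61.3% had a symbol. Where several rows shared a symbol, the row named by the table or else the row with the highest mean over all 8 libraries carried it. Names are therefore those of the best protein match, and a gene and a close copy may share reads. POU5F1 was paired with no row.

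Depth was read from the RPKM values. RPKM multiplied by query length came in multiples of 1 value per library, which implied 14400000 to 18080000 reads per library. Between 71.6% and 73.3% of values under 50 reads were whole within 0.01 of a read, against 2.0% by chance, so reads were recovered for most but not nearly all low values. Pairs of replicates differed by more than sampling noise. Their chi-square per degree of freedom was at least 7.19 over genes with at least 20 recovered reads. That does not show that the replicates were independent. Each library was counted as 1 replicate.

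Genes with at least 1 RPKM in at least 4 of the 8 libraries were tested (15597 genes). Values were transformed to log2(RPKM + 1) and compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, dome-shaped minus primed, which understates changes of low genes. Before the data were examined, 32 gene lists were fixed for the medium components and for cell types that such cultures could hold. Lists with at least 3 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 28 lists tested. In the results, the measured genes of a list are its tested members, and list genes below the filter are not counted. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Camera and fry do not relabel libraries, so an exact permutation test of each list's mean log2 value over the 70 relabellings was added after the data were seen; its smallest two-sided p is 0.0286.

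The genes named were set by a rule fixed before the data were examined: 12 genes of pluripotency always, the 6 largest changes in each direction among called genes with a symbol, a mean of at least 5 RPKM in the higher group and groups that did not overlap, and up to 4 members with the smallest adjusted p of each list described. Genes outside that rule are said to be so. One gene that the rule takes is not reported here. Alternatives were a pseudocount of 0.1 or 0.5, no filter, a mean of at least 5 RPKM, quantile normalization, median-of-ratios scaling, rescaling to an equal sum per library (TPM), the number after CES in the titles as a replicate block, averaging of both dome-shaped libraries of CES1, no trend, and leaving out each library. Limma voom on the recovered reads was added after the data were seen.

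The gene test was checked on simulated data with known changes in 15597 genes drawn from the means and spread of this comparison. It recovered 70 of 100 genes changed by a log2 fold change of 1 and 91 of 100 changed by 2, with 11 false calls. The simulated genes and libraries were independent and normally distributed, with no outlying library, so these figures may not hold for the real libraries. The labels do not say that the replicates were separate cultures or lines. P-values therefore measure only the spread between these samples, which may be technical. Dome-shaped replicates 1 and 2 share the number 1 after CES in their titles, and primed replicates 3 and 4 share the number 3. The averaging alternative covered only the dome-shaped pair.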

Results

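The series compared gene expression of primed and dome-shaped cynomolgus monkey ESCs. Primed ESCs are pluripotent cells that grow as flat epithelial colonies; the dome-shaped ESCs had been grown in a medium with LIF and inhibitors of MEK, GSK3, p38 and JNK. Each group had 4 libraries, with 16360000 to 18080000 reads implied per primed library and 14400000 to 17680000 per dome-shaped library. The libraries held 15141 to 15830 genes at 1 RPKM or more. The labels' replicate numbers were used only as names.

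Genes of epithelial junctions were lower and several mesenchymal transcription factors higher in dome-shaped than in primed ESCs. CDH1, the E-cadherin of epithelial junctions, stood at 91.8 ± 10.6 RPKM in primed and 3.02 ± 4.67 RPKM in dome-shaped cells (SD, n = 4 each). Of the 15597 genes tested by limma, 995 were higher and 1242 lower in dome-shaped than in primed ESCs, and 216 and 577 of these differed at least 2-fold. The groups did not overlap for 3462 genes, 22.2% of those tested, where chance gives 2.9% on average over relabellings. Genes vary together, so a single grouping can lie far from that average, and the 2 shares are no test of chance. The higher count fell to 381 without primed replicate 2, 516 without primed replicate 3, 487 without primed replicate 4, 399 without dome-shaped replicate 2 and 442 without dome-shaped replicate 3, and the lower count to 655, 757, 689 and 686 without primed replicate 2, primed replicate 4, dome-shaped replicate 2 and dome-shaped replicate 3. The count of higher genes at least 2-fold changed fell to 143 without dome-shaped replicate 2.

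The first principal component held 49.3% of the variance and separated the groups. Primed libraries scored from -37.0 to -28.6 and dome-shaped replicates 1 to 3 from 40.7 to 41.1, while dome-shaped replicate 4 scored 9.9. Its correlation with primed libraries across genes was 0.949 to 0.962, against 0.923 to 0.942 for the other dome-shaped libraries; genes are not independent replicates. Without dome-shaped replicate 4 the counts were 1289 higher and 1441 lower.

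**Figure D1:**
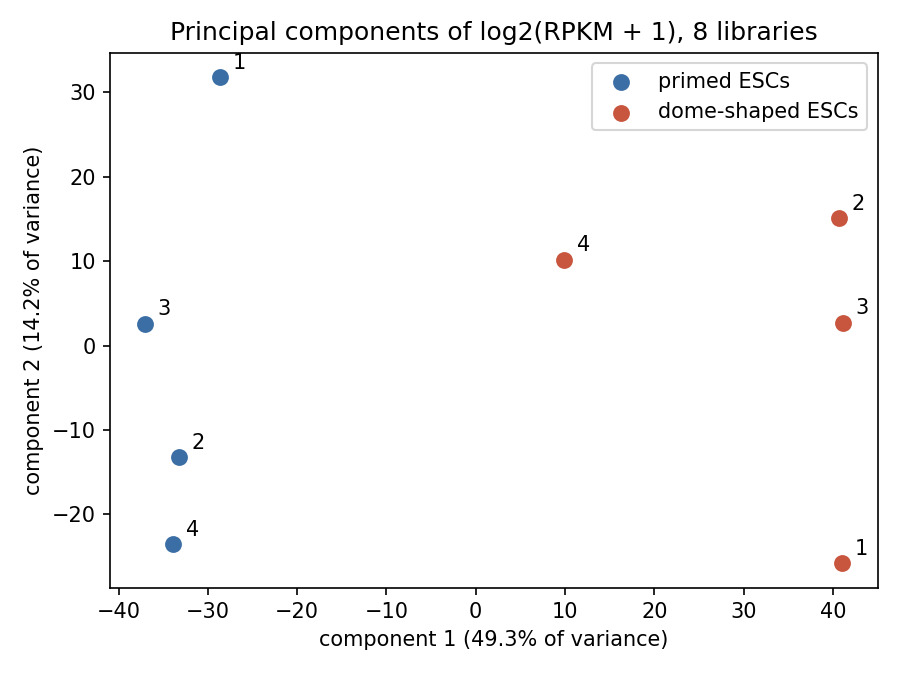
Scores of the 8 libraries on the first 2 principal components of log2(RPKM + 1) over 15597 genes; each point is a library, with its replicate number. The 4 primed libraries lie between -37.0 and -28.6 on component 1, dome-shaped replicates 1 to 3 between 40.7 and 41.1, and dome-shaped replicate 4 at 9.9.

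CRABP1, FOXB1, TWIST1, A2M and LIX1L were among the 6 largest increases with a symbol. CRABP1, a binding protein of retinoic acid, rose from 14.6 ± 9.11 to 233 ± 148 RPKM (log2 fold change 3.72, SE 0.61, adjusted p = 0.00655). FOXB1, a forkhead factor, rose by a log2 fold change of 3.59 (SE 0.27), A2M by 3.36 (SE 0.18) and LIX1L by 3.30 (SE 0.44). The 6 largest decreases were CDH1, AP1M2, LAD1, SPP1, CLDN7 and HESX1. AP1M2, a subunit of the sorting adaptor of epithelial cells, fell from 59.9 ± 20.4 to 1.00 ± 0.775 RPKM, LAD1 from 32.4 ± 7.43 to 0.627 ± 0.666 RPKM and HESX1, a homeobox gene of the anterior neural plate, from 30.5 ± 3.96 to 1.26 ± 0.399 RPKM (log2 fold change -3.81, SE 0.16, adjusted p = 1.69e-05). The AP1M2 symbol fitted 3 rows of the table. SPP1 fell by a log2 fold change of -4.04 (SE 0.68), with 2354 RPKM in primed replicate 1 and 258 to 621 RPKM in the other primed libraries.

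Of 21 measured epithelial genes, 20 were lower in dome-shaped ESCs and none was higher (21 lower when adjusted over the list alone). The median log2 fold change was -1.36 (camera adjusted p = 1.66e-18; adjusted p = 0.102 with an estimated correlation), and every dome-shaped library scored below every primed library (exact permutation p = 0.0286). CDH1 fell by a log2 fold change of -5.15 (SE 0.60, adjusted p = 0.00203). The tight junction claudins CLDN4 and CLDN7 fell by -2.87 (SE 0.17) and -3.98 (SE 0.39), RAB25, a trafficking GTPase of epithelia, by -3.56 (SE 0.34), and GRHL2, a transcription factor of epithelial genes, by -3.61 (SE 0.40). In dome-shaped replicate 4 CDH1 stood at 9.96 RPKM and GRHL2 at 3.76 RPKM, against at most 1.56 and 0.578 RPKM in the other dome-shaped libraries.

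Of 15 measured mesenchymal genes, 6 rose and none fell (7 rose when adjusted over the list alone; median log2 fold change 0.75, camera adjusted p = 0.00253; adjusted p = 0.455 with an estimated correlation; exact permutation p = 0.0286). ZEB1 and ZEB2, repressors of epithelial genes, rose by 2.85 (SE 0.40) and 3.09 (SE 0.35) on the log2 scale. TWIST1, a transcription factor of mesenchyme, rose from 3.56 ± 2.49 to 45.8 ± 16.9 RPKM. VIM, the intermediate filament vimentin, rose from 137 ± 147 to 708 ± 171 RPKM; primed replicate 1 stood at 357 RPKM and the other primed libraries at 52.5 to 76.8 RPKM. Among 9 measured fibroblast genes 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.565).

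**Figure D2:**
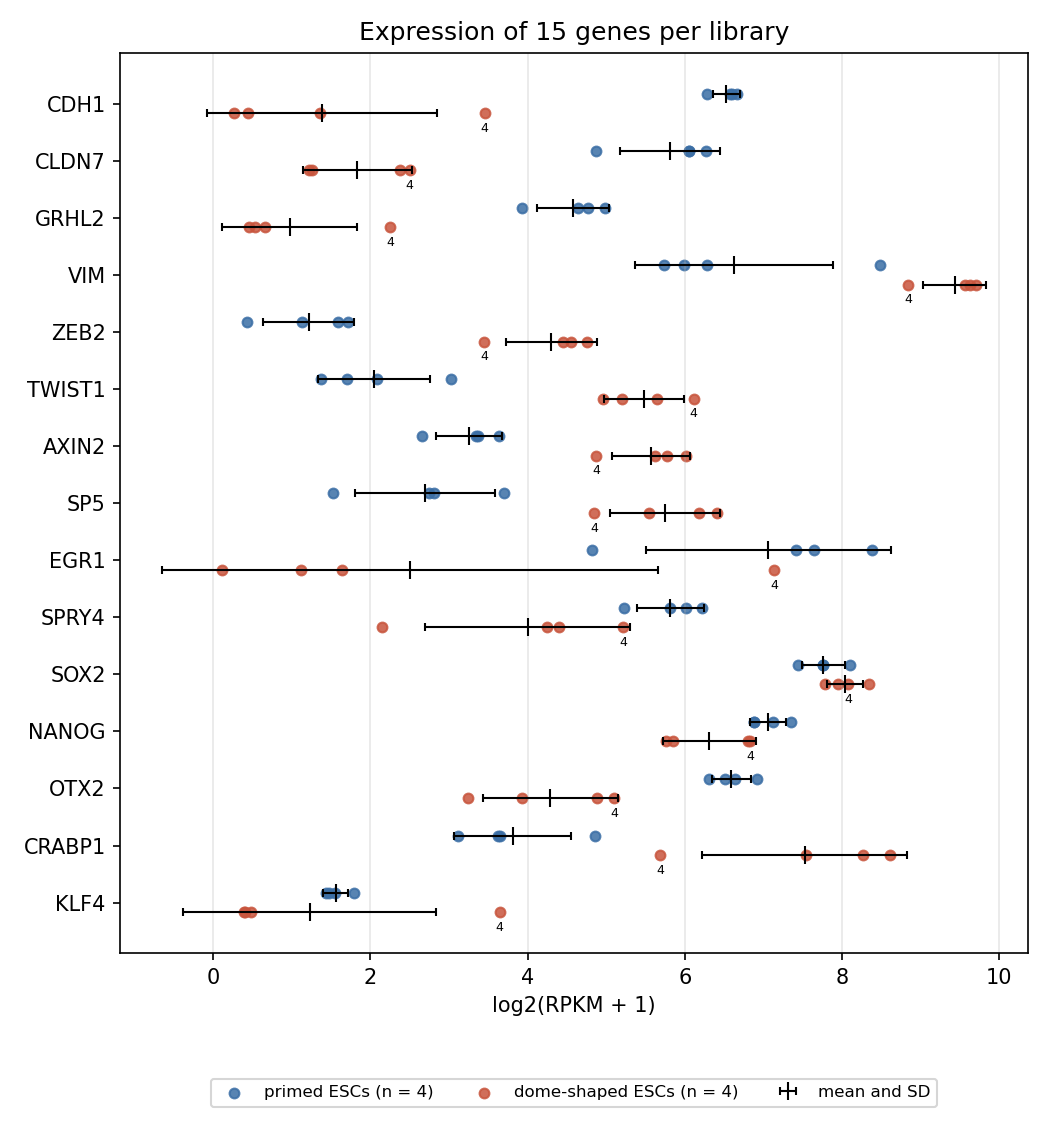
Expression of 15 genes as log2(RPKM + 1), one point per library, with the mean and SD of each group (n = 4) in black and dome-shaped replicate 4 marked. CDH1, CLDN7 and GRHL2 lie lower and VIM, ZEB2 and TWIST1 higher in every dome-shaped library, while EGR1 in dome-shaped replicate 4 (140 RPKM) lies among the primed libraries.

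Genes of the core pluripotency network were lower or not called. Of 17 measured, 7 fell and none rose (11 fell when adjusted over the list alone; median log2 fold change -0.69, camera adjusted p = 0.000139; adjusted p = 0.455 with an estimated correlation; exact permutation p = 0.0571). The list's mean score was -0.184 in dome-shaped replicate 4, within the primed range of -0.192 to 0.111, and -1.091 to -0.752 in the other dome-shaped libraries; TDGF1 stood at 273 RPKM and FOXD3 at 25.5 RPKM in replicate 4, against 21.8 to 80.1 and 1.13 to 4.54 RPKM in those. The telomere protein gene TERF1 fell from 295 ± 19.5 to 186 ± 41.5 RPKM, and the telomerase gene TERT, the NODAL co-receptor gene TDGF1 and the forkhead gene FOXD3 fell by -0.73 (SE 0.17), -2.41 (SE 0.61) and -2.45 (SE 0.64) on the log2 scale. These 4 genes stayed lower whichever library was left out, but the adjusted p of each passed 0.05 without some of them. TERF1 (log2 fold change -0.81 to -0.56 over the 8 fits) was no longer called without primed replicate 2 (adjusted p = 0.0518) or dome-shaped replicate 2 (adjusted p = 0.0522), and TERT (-0.83 to -0.65) without primed replicates 2 or 4 or dome-shaped replicate 3 (adjusted p up to 0.0713). TDGF1 (-3.04 to -1.84) was not called without any one primed library or dome-shaped replicates 2 or 3 (adjusted p up to 0.0819), and FOXD3 (-3.18 to -1.97) was called only without dome-shaped replicate 4 among these fits (adjusted p up to 0.0913 in the others). SOX2 stood at 219 ± 41.4 and 264 ± 43.8 RPKM (log2 fold change 0.27, SE 0.15, adjusted p = 0.249). NANOG stood at 134 ± 21.9 and 83.5 ± 32.9 RPKM (log2 fold change -0.75, SE 0.26, adjusted p = 0.0836); 5 rows of the table fitted its symbol. POU5F1 had no paired row. The row ENSMMUG00000015688, chosen after its values were seen because its best match was an OCT4 pseudogene protein, stood at 1771 ± 184 and 1241 ± 490 RPKM (adjusted p = 0.109), with 1956 RPKM in dome-shaped replicate 4.

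Of 10 measured genes associated with naive pluripotency, 1 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.227). The homeobox gene GBX2, which is also on the neural ectoderm list, rose from 5.38 ± 2.12 to 60.5 ± 30.1 RPKM. ZFP42 fell from 88.5 ± 10.7 to 52.3 ± 7.93 RPKM (log2 fold change -0.75, SE 0.13, adjusted p = 0.0078). VENTX and PRDM14 fell by -1.19 (SE 0.29) and -1.22 (SE 0.33); VENTX was lost without any single library but primed replicate 1 and dome-shaped replicate 4 (adjusted p up to 0.0731), and PRDM14 without any single library but dome-shaped replicates 2 and 4 (up to 0.0885). KLF4 stood at 1.96 ± 0.346 RPKM in primed cells, at 0.312 to 0.392 RPKM in dome-shaped replicates 1 to 3 and at 11.5 RPKM in replicate 4 (adjusted p = 0.768), and KLF5 at 3.05 ± 1.87 and 2.35 ± 0.945 RPKM (adjusted p = 0.752). KLF17, TFCP2L1, DPPA3 and DPPA5 were below the filter, with group means of at most 0.024, 0.237, 0.97 and 0.51 RPKM.

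Of 22 measured genes associated with primed pluripotency, 4 rose and 6 fell (6 and 9 when adjusted over the list alone, camera adjusted p = 0.177). By fry the list was lower (fry adjusted p = 0.0138), and every dome-shaped library scored below every primed library (exact permutation p = 0.0286). OTX2, a homeobox gene of primed pluripotency and the forebrain, fell from 96.6 ± 17.4 to 21.1 ± 11.6 RPKM (log2 fold change -2.30, SE 0.37, adjusted p = 0.00589). KDR fell by -1.81 (SE 0.22) and SALL2 by -0.84 (SE 0.13), and NEFL rose by 1.30 (SE 0.19). The de novo DNA methyltransferase gene DNMT3B fell from 744 ± 143 to 393 ± 186 RPKM (log2 fold change -0.998, SE 0.28, adjusted p = 0.0419), a call lost without any single library but primed replicate 1 and dome-shaped replicate 4 (adjusted p up to 0.106). Its relative DNMT3A fell by -0.55 (SE 0.12), lost without primed replicates 2 or 3 or dome-shaped replicate 2 (adjusted p up to 0.0558). Both were the 2 of 12 measured DNA methylation genes that fell, also when adjusted over the list alone, and none rose (camera adjusted p = 0.272).

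Targets of WNT signalling, the pathway that GSK3 restrains, changed in both directions in dome-shaped ESCs. Of 20 measured, 5 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.109). Dome-shaped replicate 4 had a mean score of -0.271, within the primed range of -0.702 to 0.486, and the other dome-shaped libraries 0.409 to 0.767. AXIN2, a feedback inhibitor of WNT, rose from 8.80 ± 2.55 to 48.4 ± 14.9 RPKM (log2 fold change 2.32, SE 0.27, adjusted p = 0.00203). The feedback genes NKD1 and NKD2 rose by 2.24 (SE 0.32) and 0.80 (SE 0.15), and SP5, a WNT-induced transcription factor, by 3.05 (SE 0.46). Each of these named genes was higher in every dome-shaped library, replicate 4 included, than in any primed library. AXIN2 stood at 28.3 RPKM in dome-shaped replicate 4 and at most at 11.5 RPKM in primed libraries.

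Of 22 measured feedback and target genes of ERK signalling, the pathway that MEK drives, 1 fell and none rose over all genes tested (5 fell and 2 rose when adjusted over the list alone). The median was -0.84 (camera adjusted p = 0.0186; adjusted p = 0.616 with an estimated correlation; exact permutation p = 0.0857), and the list's call was lost without dome-shaped replicate 1 (median -0.46, adjusted p = 0.229). The list's mean score was 0.078 in dome-shaped replicate 4, within the primed range of -0.307 to 0.284, and -2.10 to -0.816 in the other dome-shaped libraries. SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by -1.52 (SE 0.32, adjusted p = 0.0173), lost without dome-shaped replicates 2 (adjusted p = 0.0524) or 3 (adjusted p = 0.0522). SPRY4 stood at 57.1 ± 15.8 and 19.4 ± 13.4 RPKM (adjusted p = 0.0577) and ETV4 at 114 ± 35.4 and 42.8 ± 23.5 RPKM (adjusted p = 0.0592). The immediate-early gene EGR1 stood at 0.08 to 2.12 RPKM in dome-shaped replicates 1 to 3, at 140 RPKM in replicate 4 and at 27.1 to 333 RPKM in primed libraries (adjusted p = 0.0599).

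Of 13 measured targets of LIF and STAT3, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.266). Every dome-shaped library scored above every primed library on this list (exact permutation p = 0.0286 and 0.089 after adjustment over the lists, fry adjusted p = 0.0755). The margin was narrow, with scores of -0.063 to 0.049 in primed libraries and 0.061 to 0.118 in dome-shaped replicates 1 to 3. Dome-shaped replicate 4 scored 0.483. SOCS2, a cytokine feedback inhibitor, rose from 10.6 ± 2.53 to 32.9 ± 5.13 RPKM and STAT3 rose by 0.74 (SE 0.10) on the log2 scale. OSMR rose by 0.81 (SE 0.22), a call lost without primed replicates 2, 3 or 4 or dome-shaped replicates 2, 3 or 4 (adjusted p up to 0.102). SBNO2 fell by -0.74 (SE 0.15), a call lost with the number after CES as a replicate block (limma adjusted p = 0.0582). Of 15 measured genes of the JNK, p38 and AP-1 list none was called, also when adjusted over the list alone (median -0.85, camera adjusted p = 0.0973). Dome-shaped replicate 4 scored 0.665 on this list, above the primed range of -0.22 to 0.186, and the other dome-shaped libraries -1.436 to -0.651. Of 18 NODAL and TGF-beta targets 1 rose and 2 fell (1 and 3 when adjusted over the list alone; camera adjusted p = 0.177). FST, the activin-binding follistatin, rose from 138 ± 19.6 to 375 ± 92.2 RPKM.

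Some markers of other lineages were lower and a few were higher in dome-shaped ESCs, while most of those measured were not called. Of 8 measured trophoblast genes 4 fell and none rose, also when adjusted over the list alone (median -1.48, camera adjusted p = 0.000621; adjusted p = 0.102 with an estimated correlation; exact permutation p = 0.0286). In all, 21 trophoblast genes were found by name, and those not tested were below the filter. With no filter the trophoblast median was -0.46 (camera adjusted p = 0.000709). The 4 genes were the keratin genes KRT7 and KRT18, which are also epithelial genes, by -1.89 (SE 0.19) and -1.47 (SE 0.20), and PGF and HAND1 by -1.21 (SE 0.27) and -1.55 (SE 0.36). PGF was lost without primed replicate 3 or dome-shaped replicates 2 or 3 (adjusted p up to 0.056) and HAND1 without primed replicates 2 or 4 or dome-shaped replicates 2 or 3 (adjusted p up to 0.0639), and 9 rows fitted the KRT18 symbol. Of 7 measured neural ectoderm genes, GBX2 and FABP7 rose (3 rose when adjusted over the list alone; median 1.26, camera adjusted p = 0.00524; adjusted p = 0.344 with an estimated correlation; exact permutation p = 0.0286), FABP7 from 0.781 ± 0.156 to 4.07 ± 0.866 RPKM. The other neural ectoderm genes among the 24 found by name were below the filter and not tested. The neural call was lost with no filter (median 0.046, camera adjusted p = 0.407) and at a mean of at least 5 RPKM (camera adjusted p = 0.0566).

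Of 14 primitive streak and mesoderm genes 1 rose and 4 fell (3 and 5 when adjusted over the list alone; camera adjusted p = 0.159), and of 15 endoderm genes 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0615). FOXA2, a forkhead factor of endoderm, fell from 30.0 ± 7.14 to 5.12 ± 3.22 RPKM. Of 8 amnion genes 1 fell, also when adjusted over the list alone (camera adjusted p = 0.177). It was IGFBP3, at 22.1 ± 10.2 and 4.95 ± 2.40 RPKM.

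Some genes of lipid synthesis were higher in dome-shaped ESCs, while most of those measured were not called. Of 16 measured fatty acid synthesis genes 7 rose and none fell, also when adjusted over the list alone (median 0.43, camera adjusted p = 0.000621; adjusted p = 0.102 with an estimated correlation; exact permutation p = 0.0286). SCD, the stearoyl-CoA desaturase, rose from 146 ± 13.8 to 215 ± 18.1 RPKM, ACACA, an acetyl-CoA carboxylase, from 22.1 ± 1.21 to 32.0 ± 3.36 RPKM and ELOVL5 from 95.3 ± 13.5 to 144 ± 13.4 RPKM. Of 23 cholesterol synthesis genes 8 rose and none fell (10 rose when adjusted over the list alone; median 0.34, camera adjusted p = 0.00013; adjusted p = 0.38 with an estimated correlation; exact permutation p = 0.0286). MSMO1 and NSDHL rose by 0.63 (SE 0.10) and 0.38 (SE 0.08).

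Of 42 genes of oxidative phosphorylation 6 rose and 2 fell (7 and 2 when adjusted over the list alone; median 0.14, camera adjusted p = 0.0167; adjusted p = 0.616 with an estimated correlation; exact permutation p = 0.0286), lost without dome-shaped replicate 1 (adjusted p = 0.0873) or 4 (adjusted p = 0.0618). ATP5MC3, an ATP synthase subunit gene, rose from 217 ± 22.3 to 299 ± 13.4 RPKM; 4 rows fitted its symbol. Of 18 glycolysis genes 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.247). The lactate dehydrogenase gene LDHA rose by 0.60 (SE 0.10), and 5 rows fitted its symbol. The hexokinase gene HK1 and the glucose transporter gene SLC2A1 fell by -0.81 (SE 0.13) and -0.98 (SE 0.19). Of 20 integrated stress response genes 3 rose over all genes tested (4 rose and 1 fell when adjusted over the list alone; median 0.45, camera adjusted p = 0.0186; adjusted p = 0.616 with an estimated correlation; exact permutation p = 0.3429), lost without dome-shaped replicate 1 (adjusted p = 0.0509) or 4 (adjusted p = 0.26). SHMT2, a serine hydroxymethyltransferase gene, rose by 1.14 (SE 0.20). The list's mean score was 0.918 and 1.05 in dome-shaped replicates 1 and 4 and -0.141 and 0.035 in replicates 2 and 3.

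**Figure D3:**
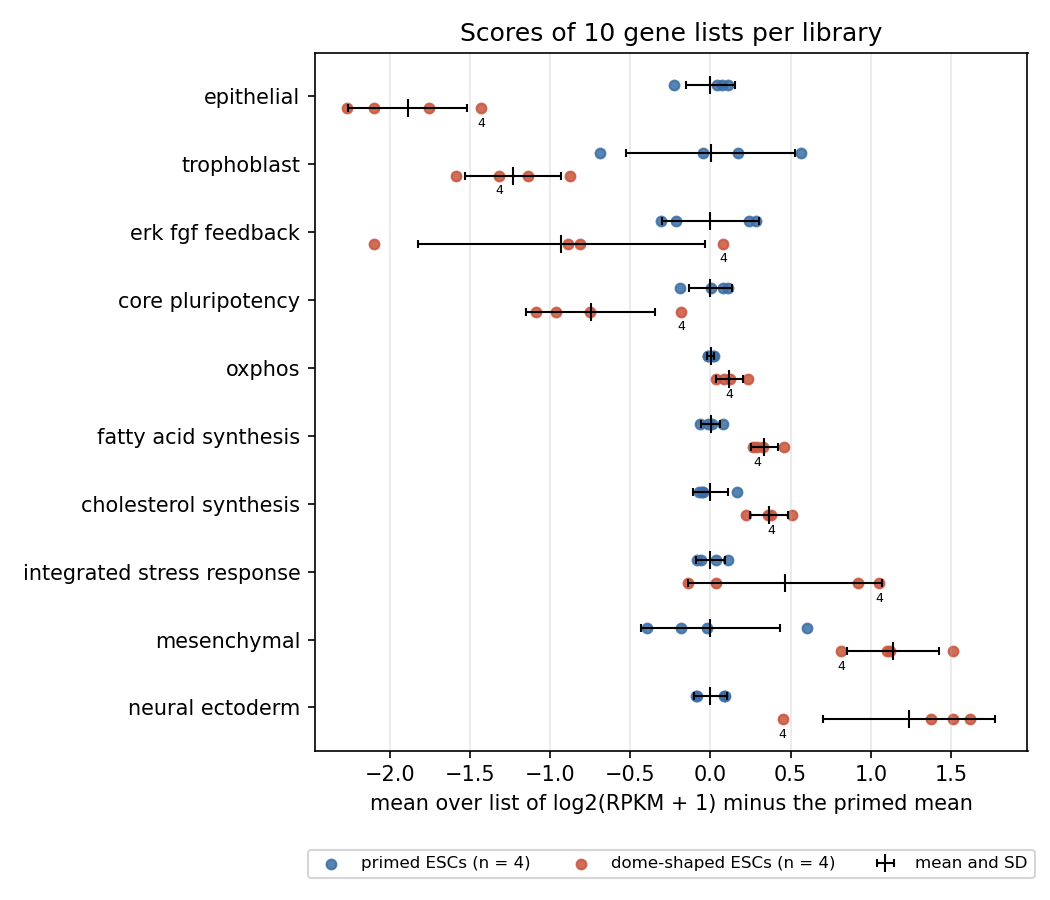
Mean over the measured genes of each list of log2(RPKM + 1) minus the primed mean, for the 10 lists past the camera threshold; one point per library, mean and SD of each group (n = 4) in black, dome-shaped replicate 4 marked. The groups do not overlap for 7 of the 10 lists, and the integrated stress response score of the dome-shaped libraries runs from -0.141 to 1.05.

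The remaining lists did not pass the list test. Of 18 hypoxia genes 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.565), with BNIP3 at 89.3 ± 14.7 and 157 ± 29.5 RPKM and CA9 at 10.4 ± 0.767 and 4.69 ± 1.43 RPKM. Of 26 extracellular matrix genes 4 rose and 1 fell (6 and 2 when adjusted over the list alone; camera adjusted p = 0.227); TNC rose from 0.544 ± 0.190 to 6.72 ± 3.92 RPKM and HSPG2 fell by -0.61 (SE 0.09). Of 27 proliferation genes 3 rose (2 when adjusted over the list alone; camera adjusted p = 0.0622). Of 12 interferon and antigen presentation genes 1 rose and 2 fell (1 and 3 when adjusted over the list alone; camera adjusted p = 0.671). Of 18 p53 targets TP53I3 fell by -0.97 (SE 0.20), also when adjusted over the list alone (camera adjusted p = 0.618), and none of 19 unfolded protein response genes was called, also when adjusted over the list alone (camera adjusted p = 0.831). Germline genes were not tested as a list, since 2 of 25 passed the filter. Of the lists kept as checks, 3 of 9 sex-linked, 0 of 13 mitochondrially encoded and 2 of 18 histone genes were found by name, too few to use.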

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

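All tests of explanations in this part were chosen after the results were seen. Single libraries were compared with the other 3 of their group; 27 of 264 groups of 4 held a library that stood far apart, where chance gives about 13.2, since about 1 in 20 groups is flagged by chance.

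Dome-shaped replicate 4 held 8 of the 27, and primed replicate 1, described below, held more. The first component score of dome-shaped replicate 4 was 9.9, against 40.7 to 41.1 in the other dome-shaped libraries. KLF4 stood at 11.5 RPKM (others 0.312 to 0.392), SPRY1 at 11 RPKM (others 3.53 to 4.19), GRHL2 at 3.76 RPKM (others 0.366 to 0.578), VIM at 456 RPKM (others 755 to 834) and HAND1 at 0.717 RPKM (others at most 0.0715). The mean score of its LIF and STAT3 list was 0.483 (others 0.061 to 0.118) and that of its endoderm list -1.92 (others -0.282 to -0.222).

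Primed cells mixed into this culture would need 1 share of primed cells for all genes. Over 144 genes at least 4-fold lower in the other dome-shaped libraries that share had a median of 17.9% (95% bootstrap interval 14.2 to 21.7), and over 61 genes at least 4-fold higher a median of 80.8% (72.9 to 92.9), so the medians differed by 62.9 percentage points, which argues against a plain mixture as the whole cause. Low depth is argued against by dome-shaped replicate 2, which had 14400000 reads, against 14410000 in replicate 4, and scored 40.7 on the first component. A primed library under a dome-shaped label would need a share near that of a wholly primed culture in both sets, which the 17.9% argues against, while a sample from outside these groups under this label and a difference in culture were not tested and stay open.

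Primed replicate 1 stood apart for LIX1L (9.19 RPKM, others 1.07 to 1.61), ZEB1 (3.40 RPKM, others 0.233 to 0.5) and SPRY1 (24.6 RPKM, others 14), which were higher there. It was lower for DNMT3B (533 RPKM, others 793 to 852), AP1M2 (29.7 RPKM, others 66.9 to 75), CLDN7 (28.3 RPKM, others 65.3 to 76.2) and ID3 (114 RPKM, others 192 to 204). Its row ENSMMUG00000015688 stood at 2050 RPKM (others 1670 to 1690), its DNA methylation list score at -0.111 (others 0.032 to 0.045) and its unfolded protein response score at 0.054 (others -0.023 to -0.012).

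CCN2 stood at 510 RPKM and WARS1 at 71.7 RPKM in primed replicate 2, against 268 to 288 and 69.3 RPKM in the other primed libraries. In primed replicate 3, PDGFRB stood at 7.25 RPKM (others 9.85 to 10.1), BNIP3 at 111 RPKM (others 81.4 to 82.4), TMPRSS2 at 8.52 RPKM (others 19.6 to 22.4) and the cholesterol synthesis score at 0.164 (others -0.069 to -0.044). In dome-shaped replicate 1 ZFP42 stood at 40.4 RPKM (others 55.8 to 57.0). In dome-shaped replicate 3 SALL2 stood at 119 RPKM (others 92.5 to 96.1) and ID3 at 165 RPKM (others 46.5 to 50.3).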

How the results depend on the processing

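Voom on recovered reads and the exact permutation of list scores were chosen after the data were seen. Higher and lower counts (995 and 1242; 216 and 577 at least 2-fold) stayed within 1.5 times under both pseudocounts, no filter, the 3 scalings, no trend, averaged CES1 libraries and voom (1018 and 1281). A mean of at least 5 RPKM, which tests 11129 genes, gave 131 and 311 at least 2-fold. Leaving out single libraries gave 381 to 1289 higher, 655 to 1441 lower, 143 to 321 and 407 to 696 at least 2-fold, and 8 to 14 lists against 10; fewer samples enter those fits. With the number after CES as a replicate block, 303 rose and 593 fell, with 125 higher at least 2-fold. Those numbers were not found to pair the samples: deviations of same-number libraries correlated at -0.10 to 0.12, and 2 of 8 libraries correlated best with their own number. Lists past the threshold numbered 0 with an estimated correlation, 8 by fry and 0 by exact permutation after adjustment. Fry added the primed pluripotency list (fry adjusted p = 0.0138). It did not call the ERK (0.277), oxidative phosphorylation (0.13) and integrated stress response (0.277) lists. Estimated inter-gene correlations of the 10 lists ran from 0.002 (trophoblast) to 0.583 (integrated stress response), against the preset 0.01. The trophoblast call was lost with the estimated correlation too. The cause of these differences was not tested further. For the exact test, 4 against 4 libraries allow no p under 0.0286. KLF4, not called, turned to a log2 fold change of 0.072 under the block and KLF5, not called (-0.447 to 0.044 over the fits without 1 library), to 0.044 without primed replicate 3; the cause was not tested. Of 92 called named genes, 62 kept their call in every alternative that gave a value. A quasi-likelihood count test was planned only for a table of whole-number counts and was not run, as the table held RPKM values. Of low values, 71.6% to 73.3% came out whole as recovered reads. A depth of 14400000 to 18080000 reads limits values under 1 RPKM. Genes with at least 1 RPKM in fewer than 4 libraries were not in the main test.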

Other observations

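All tests in this part except the splits of the libraries were chosen after the results were seen, and the genes of the first paragraph were picked by their values.

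Several genes outside the rule for named genes, chosen after their values were seen, were called between dome-shaped and primed ESCs. ST14, the protease matriptase, fell from 26.4 ± 4.42 to 1.66 ± 1.05 RPKM and its partner PRSS8 from 74.2 ± 4.87 to 21.8 ± 6.38 RPKM (SD, n = 4 each). The protease inhibitor genes SPINT1 and SPINT2 fell by -3.27 (SE 0.36) and -0.82 (SE 0.12) on the log2 scale, TMPRSS2 by -2.54 (SE 0.30) and OVOL2, an epithelial transcription factor, by -2.78 (SE 0.41). SHISA2 fell by -3.42 (SE 0.42). The WNT receptor gene FZD10 rose from 1.88 ± 1.21 to 17.9 ± 8.21 RPKM while FZD5 fell by -1.90 (SE 0.36). FZD8 fell by -1.28 (SE 0.30), a call lost without primed replicates 2 or 4 or dome-shaped replicates 1, 2 or 3 (adjusted p up to 0.0659).

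Lower epithelial and higher mesenchymal genes could come from other cells in the dome-shaped cultures. Cells that replaced ESCs and lacked the whole core pluripotency list would lower its genes as far as CDH1. CDH1 kept 3.3% of its primed level (0.8% without dome-shaped replicate 4), and the epithelial list kept a median of 38.2% (31.6% without it). The 17 core pluripotency genes kept a median of 63.0% (57.3% without it), with SOX2 highest at 120.7%. FOXD3 was lowest at 27.0% (8.9% without it), and TDGF1 at 27.2% (13.4% without it) also lay below the epithelial median. The test cannot decide on cells of another type that keep part of the core list. Nor can it decide on a smaller share of cells that lack the list, which would lower its genes only in part. Fibroblasts would bring collagen with VIM: the 5 collagen genes of the fibroblast list changed by -29.8 RPKM in sum while VIM changed by 571 RPKM. Scaling between the libraries left the epithelial median at -1.36 or lower. These values argue against scaling and against fibroblasts as the source. They also argue against replacement by cells that lack the whole core list as the cause of the fall of CDH1. A smaller share of such cells beside the ESCs was not tested and stays open, as do cells that keep part of that list. A change of the ESCs themselves, with the medium, remains as a hypothesis found and tested on the same data.

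Of the 35 splits of the 8 libraries into 4 and 4, only the real one called as many genes (2237, and 5 in the highest other split). It was also the only 1 of 35 to call as many at least 2-fold (793, highest other 5). No split can be rarer than 1 of 35, and the other splits hold the group difference in their residual spread. These counts therefore do not exclude chance. For the lists, 8 of the 35 splits put at least 10 lists past the camera threshold, with 18 in the highest other split. This points to lists whose genes vary together between libraries. The list calls of camera with the preset correlation are therefore descriptions of these libraries.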
